A study of Oryza sativa with 78 samples.

How the data were processed

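Leaf RNA of field-grown rice (Koshihikari, Toyama, 2013) was measured on 39 two-colour Agilent arrays, each holding a sample in the Cy3 channel and another in the Cy5 channel, which gives 78 samples in 6 series of 13. Per the labels, total RNA was extracted with a Promega Maxwell 16 instrument and labelled with the Low Input Quick Amp kit. Per the file headers, Agilent Feature Extraction 10.5.1.1 gave for each spot and channel the mean spot intensity, the median local background intensity, a processed signal intensity and 0 or 1 flags. The deposited series table holds log2 values of 125722 probes that rank almost exactly as the processed signal of each sample's own channel and share a distribution across samples. The authors name Feature Extraction and the affy package for that table. These log2 values were used here as an alternative only.

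The arrays carry 156732 spots, of which 4854 are controls and 151878 are probes of 60 bases. After 1007 probes with an outlier flag were left out, 150871 remained, with 147868 distinct sequences. Mean intensity was corrected for the background median with limma's normexp method and an offset of 50. Loess normalization was applied within each array with control spots at weight 0, quantile normalization was applied to the average intensities between arrays, and each channel was then used as a log2 value. A probe was tested if it was well above background in at least 13 of the 78 samples, which left 98393 probes. No tested probe was saturated.

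Results are per probe, not per gene. None of the 151878 probe names matched the reference table of 39387 genes (assembly ASM3414082v1), so 0 were matched, and the files do not pair probe IDs with gene names. For the same reason 21 lists with 182 genes, fixed before the data were examined, could not be tested, and the rule of naming the largest changes by gene could not be used in full. Probes are therefore named by the IDs of the files, and few are named. For the shared rhythm they are those with the largest peak-to-trough ratio in each 6 h span of the day. For each comparison of levels they are among those with the largest rises and falls. For the comparison of curves between dates they are among those with the smallest p. Probes can share sequence. The tested probes form 65345 groups that overlap by at least 30 bases, 42747 of them with a single probe.

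All tests were run with limma 3.58.1 (R 4.3.3, statmod 1.5.0). A linear model held, for each series, a mean and the cosine and sine of a 24 h cycle, and a dye term. Array was a random block with a consensus correlation of 0.437 estimated on 5000 probes. Variances were moderated with a trend and robust estimation, with 59 residual degrees of freedom and a median residual SD of 0.24 (log2). P-values are two-sided and were adjusted by Benjamini and Hochberg's method over the tested probes of each comparison. A probe was called at an adjusted p under 0.05 and a change, or a fitted peak-to-trough ratio, of at least 2-fold. Tests of a difference between daily curves used the adjusted p alone. The 24 h repeat was tested on the 6 differences between the 10:00 samples, with limma. A mean over a day is given with the SD over the hours of that day, which contains the daily rhythm, and an SE comes from the model. Figures were drawn with Matplotlib 3.10.9 and values were read with NumPy 2.4.6 under Python 3.11.15.

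The labels do not state whether the 13 samples of a series came from separate plants, and each date is 1 day, so a p-value measures differences against the spread of samples about the fitted curve and not against the spread between days. Arrays fell on 11 slides, 4 of which held 2 series, and on 3 scan sessions with 2 scanners. The first 4 samples of the 54-day series had a session of their own. The July 31 series had another, so for the comparisons of July 31 with the other dates the scan session and the date cannot be told apart. The remaining samples shared the other session. Where a slide held 2 series, 10:00 was the clock hour at which both were on it. On 3 arrays these 10:00 samples of different series were the 2 channels, and the sign of their difference was compared with calls from a fit without those samples. Slide was also used as a block.

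Depth was limited by the arrays' signal. Between 78581 and 97212 probes per sample (51.74% to 64.01%) were well above background, and the upper quartile of signal over background lay between 10.03 and 46.06. The number of arrays limits the precision.

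The sampling slots pair the samples of any pair of series, since the labels give the same clock hours. This was checked by correlating, across probes, each sample's deviation from its series mean. The lowest same-slot correlation was 0.23. The number of slots whose best match was the same slot ranged from 5 of 13 (55 and 34 days) to 13 of 13 (54 and 34 days).

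On 2 arrays of the 75-day series the channels were nearly equal. The model kept all 78 samples as labelled. In a mean and SD of a named probe each of those pairs was averaged, so that 75 days has n = 11, and counts without those 4 samples are given.

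The steps were tested on simulated data with 98393 probes, the residual spread of the real data and 200 changed probes per comparison at an effect of 1.5 (log2). The shared rhythm was recovered for 197 of 200, with 2 other calls and a median peak error of 0.15 h. A difference of level between plantings on July 31 was recovered for 195 of 200, with 0 other calls. A 2 h shift between plantings was recovered for 104 of 200, with 7 other calls, and a rhythm lost between dates for 153 of 200, with 9 other calls. For a fit of differences between plantings at matched hours, 99 of 200 were recovered with 18 other calls, a larger share of wrong calls than the threshold promises. The differences of rhythm between plantings and between dates exceeded it slightly (7 beside 104 and 9 beside 153). For the rhythm of single series there were 18 other calls beside 163 at 34 days and 15 beside 161 at 54 days. There were 15 beside 160 at 55 days and 13 beside 157 at 77 days. At 75 and 97 days there were 8 beside 163 and 4 beside 160. Correct calls of further probes simulated with a rhythm are not in these single-series counts, so their share of wrong calls cannot be read from them.

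Set before the data were examined were the scanner's processed signals, the authors' values, no loess, no filter on dim probes or a filter at 39 samples, no dye term, no array block, slide in place of array as the random block, 24 h and 12 h harmonics, clock hour as a factor, slot as a block, leaving out the last sample of each series, and leaving out each series. The median of all probes of a gene, also set before the data were examined, was not run because probes have no genes here. Chosen after seeing the data were leaving out the first 4 samples of the 54-day series, the 4 samples with nearly equal channels, the last 3 samples or 3 evening samples of each series, slide as a fixed block, and the fit of differences between plantings at matched hours. That last fit was first run without a block of arrays, and the block was added after its count had been seen. Both counts are given.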

Results

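Gene expression in rice leaves was followed over 24 h in a paddy field at Toyama in 2013, on 3 dates (June 18, July 9 and July 31), in 2 plantings transplanted on April 25 (early) and May 15 (late). Leaves were sampled every 2 h from 10:00 to 10:00 of the next day. Each combination of planting and date is a series of 13 samples, which makes 6 series and 78 samples. The early planting was sampled at 54, 75 and 97 days after transplanting and the late planting at 34, 55 and 77 days. The labels state no replicates. Age is the date minus the transplanting date, so date, age and planting cannot all be varied apart, but pairs of series of nearly equal age occur on different dates.

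Between 78581 and 97212 of the probes on the array were well above background in each sample. The upper quartile of signal over background was lowest in the 34-day series, at 10.03 to 21.61, and reached 46.06 in the 97-day series. Principal components were taken over the brighter tested probes only, those that pass the stricter filter on dim probes listed among the alternatives. Over these the first component held 32.2% of the variance, of which 92.9% followed the clock hour. The second held 22.3%, with 96.8% by clock hour. The third held 12.8%, of which 89.7% followed the series. The dye accounted for 0% of each of these components. Loess within arrays brings the channels together, so a share near 0 was largely set by that step. In limma 18917 tested probes (19.2%) had a dye effect at an adjusted p under 0.05, and 0 of them reached 2-fold.

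The first question was which probes change over the day in all series together. A shared 24 h rhythm with a peak-to-trough ratio of at least 2 was called for 30688 of 98393 probes (31.2%). At an adjusted p under 0.05 without the ratio the count was 87639. The called probes fell in 20003 of 65345 groups of overlapping probes (30.6%). By 6 h span of the day, 22.6% peaked between 0 and 6 h, 23.7% between 6 and 12 h, 27.8% between 12 and 18 h and 25.9% between 18 and 24 h. In bins of 2 h the most probes peaked between 6 and 8 h (3586) and between 16 and 18 h (3490), and the fewest between 10 and 12 h (1570). A ratio of at least 16 was reached by 1552 probes, of which 40.2% peaked between 6 and 12 h and 36.9% between 12 and 18 h.

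**Figure D1:**
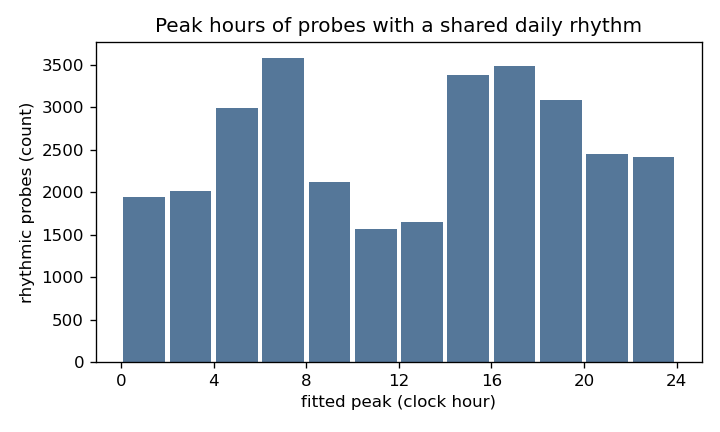
Number of probes with a shared daily rhythm (vertical axis) by fitted peak in clock hours (horizontal axis, bins of 2 h). The bins from 6 to 8 h (3586 probes) and from 16 to 18 h (3490 probes) are the highest, and the bin from 10 to 12 h (1570 probes) is the lowest.

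The files do not pair probe IDs with gene names, so probes are named by their IDs. The largest rhythm with a peak between 0 and 6 h was that of eAry2_38876, with a peak at 3.4 h, a mean peak-to-trough ratio of 824 and an adjusted p of 1.08e-36. Between 6 and 12 h it was 44kb3_960, with a peak at 7.4 h, a ratio of 889 and an adjusted p of 4.01e-35. Between 12 and 18 h it was eAry2_48790, with a peak at 16.1 h, a ratio of 2630 and an adjusted p of 5.32e-32. Between 18 and 24 h it was 44kb3_18039, with a peak at 19.0 h, a ratio of 1540 and an adjusted p of 2.93e-34. The ratio of eAry2_38876 was lowest in the 34-day series (395) and highest in the 77-day series (1570). The troughs of 44kb3_960 and 44kb3_18039 reached background, with 72 and 71 of 78 samples well above it, and the ratios depend on the processing. On the log2 scale the ratios of eAry2_38876, 44kb3_960, eAry2_48790 and 44kb3_18039 were 9.69, 9.80, 11.36 and 10.59 here and 10.80, 11.60, 11.72 and 12.24 with the scanner's processed signals.

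**Figure D2:**
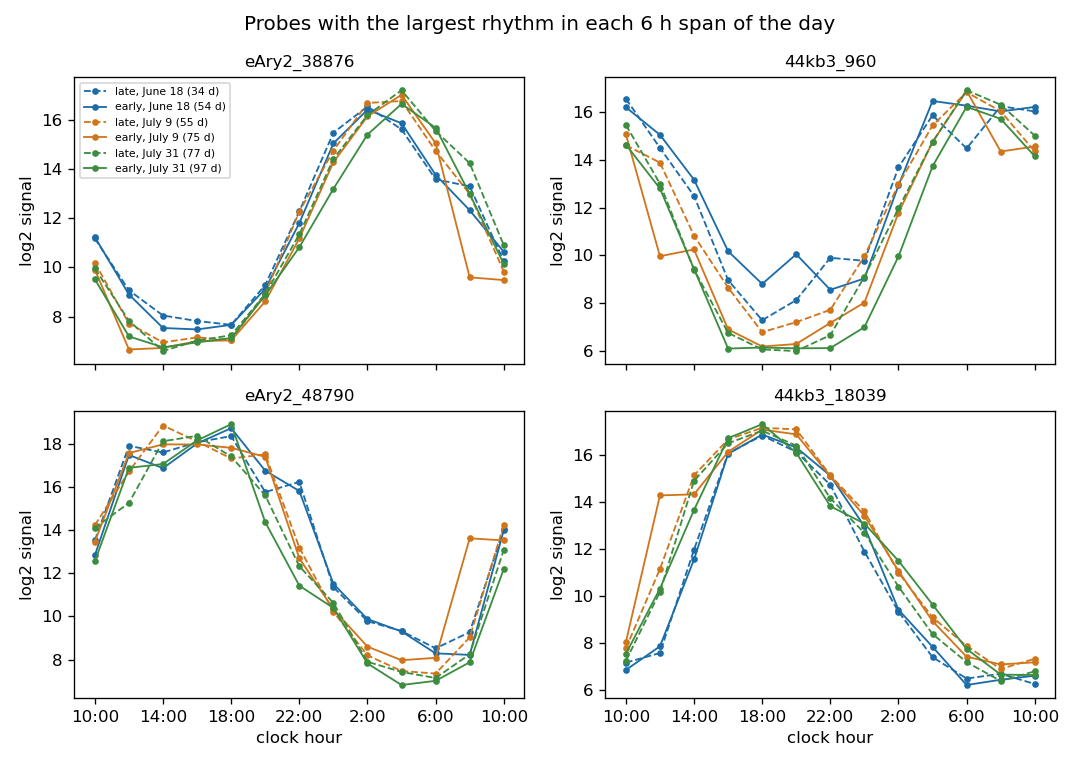
Log2 signal (vertical axes) by clock hour (horizontal axes) of the probe with the largest rhythm in each 6 h span of the day, with a line per series, solid for the early and dashed for the late planting, coloured by date. The fitted peaks lie at 3.4, 7.4, 16.1 and 19.0 h.

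Taken singly, the series held 35382 rhythmic probes at 34 days, 34383 at 54 days, 32968 at 55 days, 28055 at 75 days, 34391 at 77 days and 28633 at 97 days. A rhythm was called in all 6 series for 16079 probes and in none for 46462. Without the 4 samples of the 75-day series on arrays with nearly equal channels, that series had 30672 rhythmic probes. Over the probes with a shared rhythm the median peak-to-trough ratio was 3.38 at 34 days, 3.26 at 54 days, 3.23 at 55 days, 2.86 at 75 days, 3.36 at 77 days and 2.90 at 97 days.

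The next question was whether the plantings differ in their daily curves. In limma no probe passed, with a smallest adjusted p of 0.155. At an unadjusted p under 0.05 there were 2809 probes, where 4920 are given by chance. By date the counts were 1 on June 18, 3 on July 9 and 231 on July 31. Differences taken between the plantings at each matched hour, a fit chosen after seeing the data, gave 3943 probes (4.01%), with a median peak-to-trough ratio of the difference, averaged over the dates, of 1.40 and 269 probes at 2-fold or more. Without the 4 samples with nearly equal channels that fit gave 1058 probes. Its counts by date were 972, 94 and 18479 with all samples, and 532, 7 and 19701 without those 4. With all samples the median ratios by date were 1.86, 2.59 and 1.67, and 370, 85 and 4903 probes reached 2-fold.

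Peak hours of the plantings were compared over the probes called in both series. On June 18 the early planting peaked a median of -0.11 h from the late planting. On July 31 the median was 0.34 h (quartiles -0.18 and 0.92 h) over 24827 probes, and 94.1% lay within 2 h. On July 9 it was -0.30 h with all samples and 0.06 h without the 4 samples with nearly equal channels, so those samples decide that value. The ratio of amplitudes on July 9 was 0.916 with them and 1.007 without them. On June 18 it was 0.972, and on July 31 it was 0.924. These shifts and ratios were not tested.

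Daily curves differed between the 3 dates for 37840 probes (38.5%), at an adjusted p under 0.05 with no threshold of size. July 9 against June 18 gave 39857, July 31 against June 18 gave 32166 and July 31 against July 9 gave 136. For July 9 against June 18 the early planting gave 11078 and the late planting 13699, and 55 days on July 9 against 54 days on June 18 gave 7690. Across probes, the change of the curve from June 18 to July 9 had a correlation of 0.812 between the plantings, which share no sample, and that from July 9 to July 31 had one of 0.236. Probes are not independent replicates. Over the probes rhythmic in both series, late-planting peaks on July 9 lay a median of -0.2 h from June 18 (quartiles -1.1 and 0.71 h). The ratio of amplitudes was 0.971. In the early planting these were -0.27 h and 0.943, or 0.04 h and 1.024 without the 4 samples with nearly equal channels. These sizes were not tested. The smallest adjusted p was that of eAry1_19051 (2.91e-15), whose peak-to-trough difference (log2) was 3.39 at 34 days and 2.58 at 54 days, 0.96 and 0.80 on July 9 at 55 and 75 days, and 1.34 and 0.95 on July 31 at 77 and 97 days. It was well above background in 44 of 78 samples, 7 or 8 of 13 in each series, so these differences are against values near background. The peak-to-trough differences (log2) of 44kb3_11397 (adjusted p 1.32e-12) were 2.51 and 2.14 on June 18, 0.53 and 0.38 on July 9 and 0.22 and 0.37 on July 31, in the same order.

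Mean levels over the day were compared between the plantings on each date. On June 18, 182 probes differed, 92 higher and 90 lower in the early planting. This count depended on samples and blocks. It was 758 without the first 4 samples of the 54-day series, which were scanned apart, 28 with slide as the random block and 71 with slide as a fixed block. On July 9, 837 probes differed (250 higher and 587 lower), and 505 did (131 higher and 374 lower) without the 4 samples with nearly equal channels. With slide as a fixed block the count was 12993. On July 31, 2852 probes differed (2120 higher and 732 lower). With the scanner's processed signals and the authors' values more differed and a smaller share was higher, as given below. With slide as a fixed block 4317 differed. Standard errors were 3.54 (June 18), 2.76 (July 9) and 2.26 (July 31) times larger with that block. Of the called probes, 77.5% kept their sign with it on June 18, 95.6% on July 9 and 98.4% on July 31, but 9 of 182, 637 of 837 and 1508 of 2852 were called with it in the same direction. On the array that held 10:00 samples of both July 31 series, 93.9% of 2710 probes called without those samples had the same sign. They were the last sample of the early and the first of the late planting, so they were taken 24 h apart. The planting difference itself differed between the dates for 16885 probes (17.2%).

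On June 18, probe 44kb3_23620 had a log2 mean of 9.34 ± 0.74 (SD, n = 13) in the early planting and 6.88 ± 0.28 (SD, n = 13) in the late planting, a difference of 2.50 ± 0.19 (SE) with an adjusted p of 2.07e-14, higher at 13 of 13 hours. Probe 44kb3_31676 had a log2 mean of 8.39 in the early and 11.95 in the late planting, a difference of -3.42 ± 0.42 (SE) with an adjusted p of 5.12e-08, lower at 13 of 13 hours. In the late planting 44kb3_23620 was well above background in 9 of 13 samples, and its difference was 3.84 with the authors' values. In the main processing the largest rise on June 18 was that of eAry2_40456, at 2.76 ± 0.84 (SE) with an adjusted p of 0.0477 and 12 of 13 hours. This probe was well above background in 8 of 13 late samples and did not pass with slide as the random block. With the scanner's processed signals its difference was 3.80.

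On July 9, 44kb3_20027 was higher in the early planting by 3.04 ± 0.41 (SE, log2), with an adjusted p of 3.14e-07 and 13 of 13 hours. Probe eAry1_24857 differed by -2.83 ± 0.46 (SE, log2), with an adjusted p of 1.52e-05 and 13 of 13 hours, and by -4.27 with slide as the random block. On July 31, 44kb3_31594 had a log2 mean of 11.61 in the early and 8.09 in the late planting, a difference of 3.55 ± 0.56 (SE) with an adjusted p of 1.25e-06 and 13 of 13 hours. With the scanner's processed signals it was 4.35, and 11 of 13 late samples were well above background. Probe 44kb3_10697 differed by -3.66 ± 0.78 (SE, log2) with an adjusted p of 0.000224 and 12 of 13 hours. With slide as the random block its difference was -1.88 and it did not pass.

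Calls were set side by side between dates, which share no sample, though series of June 18 and July 9 shared some arrays and slides. The counts by chance multiply the shares called and take probes and calls as independent, which overlapping probes are not. Opposite calls exceeded them for June 18 with both other dates, so an excess over them does not by itself show agreement. June 18 and July 9 had 22 probes higher on both (0.234 are given by chance) and 2 lower on both (0.537 by chance), and 10 went opposite ways (0.778 by chance), with a correlation across probes of -0.064. June 18 and July 31 had 14 higher (1.98 by chance) and 28 lower (0.67 by chance) on both and 14 opposite (2.62 by chance), with a correlation of 0.297. July 9 and July 31 had 73 higher (5.39 by chance) and 112 lower (4.37 by chance) on both and 14 opposite (14.5 by chance), with a correlation of 0.331. On at least 2 dates 103 probes were higher and 142 lower in the early planting. On all 3 dates 3 were higher and 0 lower. Of the probes higher and lower in the early planting, which were chosen by their mean over the day, 51.1% and 61.1% kept their direction at all 13 hours on June 18, 85.2% and 96.3% on July 9, and 90.4% and 69.1% on July 31. On July 31 the median difference (log2) at 12:00 was 0.85 for the higher and -0.48 for the lower probes, and at 0:00 it was 1.88 and -2.17.

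**Figure D3:**
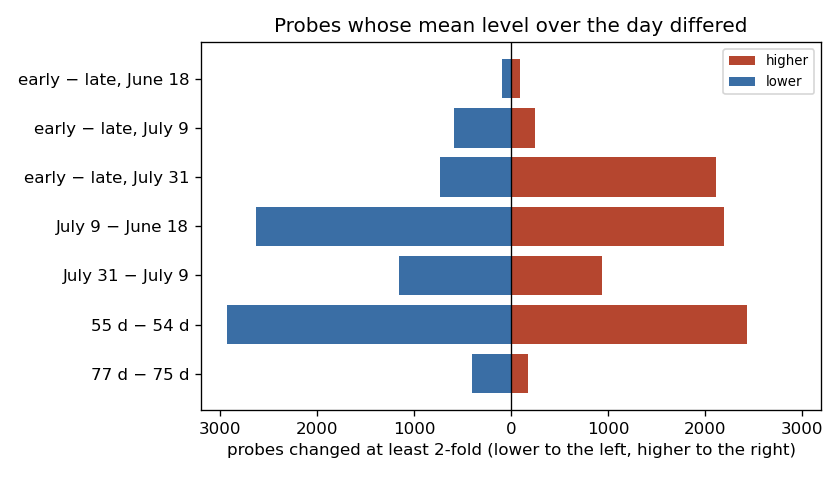
Number of probes whose mean level over the day differed at least 2-fold at an adjusted p under 0.05 (horizontal axis), higher to the right and lower to the left, for each comparison of series. The comparison of 55 days with 54 days has 2434 higher and 2934 lower, and the planting comparison on June 18 has 92 higher and 90 lower.

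Levels were then compared between dates over both plantings. From June 18 to July 9, 4830 probes changed, 2195 higher and 2635 lower on July 9. The more frequent direction turned with the scanner's processed signals (6261 higher and 5041 lower), with the authors' values (5049 and 4423) and with slide as a fixed block (5134 and 4145). With that block 9279 probes changed, with 98.7% of the called probes keeping their sign and 3675 called in both. On the arrays that held 10:00 samples of both dates, 91.8% of 4485 probes (early) and 94.6% of 5964 probes (late) called without those samples had the same sign. The plantings taken singly gave 4774 (early) and 6171 (late), of which 1239 were higher and 1634 lower in both, with a correlation across probes of 0.781. From July 9 to July 31, 2097 probes changed, 938 higher and 1159 lower. More changed with the scanner's processed signals and with the authors' values, as given below. The scan session differed between these dates, and no fit could separate it from the date. The early planting gave 3729 and the late planting 1867, with 247 higher and 636 lower in both and a correlation of 0.503.

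Probe 44kb3_35348 was 37.3-fold higher on July 9 than on June 18, a difference of 5.22 ± 0.38 (SE, log2), with an adjusted p of 2.43e-18 and 25 of 26 matched hours. Its log2 mean was 11.39 ± 1.42 (SD, n = 13) at 54 days and 17.05 ± 0.63 (SD, n = 11) at 75 days. Probe 44kb3_22232 changed by -4.49 ± 0.35 (SE, log2), with an adjusted p of 4.34e-17, and was lower at 26 of 26 hours. With slide as the random block it changed by -5.14. From July 9 to July 31, 44kb3_10988 rose by 4.67 ± 0.16 (SE, log2), with an adjusted p of 6.66e-34 and 26 of 26 hours. It was well above background in 3 of 13 samples at 55 days and 9 of 13 at 75 days, and in 13 of 13 at 77 and at 97 days, so the difference is against values near background, and it was 6.72 with the scanner's processed signals. Probe eAry1_19738 changed by -3.59 ± 0.28 (SE, log2), with an adjusted p of 1.57e-16 and 26 of 26 hours, and by -4.47 with the scanner's processed signals.

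Series of nearly equal age on different dates address whether date matters at a given age. Between 55 days on July 9 and 54 days on June 18, 5368 probes differed, 2434 higher and 2934 lower at 55 days. Which direction was the more frequent depended on the processing, with 6614 higher and 5658 lower with the scanner's processed signals, 5244 and 4877 with the authors' values, 3206 and 2963 with slide as the random block and 9198 and 7697 with slide as a fixed block. Without the first 4 samples of the 54-day series the count was 7392, and with slide as a fixed block it was 16895, with 3094 of the 5368 called in the same direction. Between 77 days on July 31 and 75 days on July 9, which were also scanned in different sessions, 577 probes differed, 171 higher and 406 lower, against 238 with slide as the random block, 1542 with the scanner's processed signals and 1280 with the authors' values. At 55 against 54 days, 44kb3_44743 differed by 5.08 ± 0.60 (SE, log2; adjusted p 3.65e-10; 13 of 13 hours) and 44kb3_29596 by -5.16 ± 0.45 (SE, log2; adjusted p 2.49e-14; 13 of 13 hours). With slide as the random block the first of these was 6.13. At 77 against 75 days, 44kb3_10697 differed by 4.68 ± 0.79 (SE, log2), with an adjusted p of 2.64e-05 and 12 of 13 hours, and by 5.64 with the scanner's processed signals. Probe eAry1_30472 differed by -3.97 ± 0.49 (SE, log2), with an adjusted p of 2.8e-08 and 13 of 13 hours. At 77 days eAry1_30472 was well above background in 4 of 13 samples, and its difference was -6.55 with the scanner's processed signals. Each of these pairs of series also differs in planting, so date and planting vary together in them.

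Every series began and ended at 10:00, which allows a comparison of samples 24 h apart. These samples lay on different slides in all 6 series, and at 54 days also in different scan sessions and scanners. Most pairs of samples 4 h apart, which are compared with them below, shared a slide. What slide and session add to the difference was not tested. Over the 6 series 130 probes differed, 89 higher and 41 lower in the second sample, and 18073 had an unadjusted p under 0.05. Chance could not be excluded for this count, since turning the signs of the differences in part of the series gave as many probes in 2 of 32 patterns, the real one included, and up to 468. Probe 44kb3_10369 differed by 3.11 ± 0.30 (SE, log2, n = 6; limma, adjusted p 0.0281) and was higher in 6 of 6 series. The 6 differences come from 3 dates with both plantings on each, and the test took them as independent. The share of probes that differed at least 2-fold was 16.39% at 34 days and 13.47% at 54 days, both on June 18, and 3.96%, 5.00%, 4.18% and 2.33% at 55, 75, 77 and 97 days. Across probes the 24 h difference had a correlation between the plantings of 0.838 on June 18, 0.826 on July 9 and 0.165 on July 31, so the plantings of a date were not independent on June 18 and July 9, and the p-value and the sign patterns do not allow for this. The median absolute log2 difference of samples 24 h apart was larger than the mean for samples 4 h apart in both June 18 series (0.391 against 0.300 at 34 days and 0.369 against 0.294 at 54 days). It was smaller in the 4 July series (0.199 against 0.239 at 55 days, 0.225 against 0.232 at 75 days, 0.227 against 0.254 at 77 days and 0.175 against 0.227 at 97 days).

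**Figure D4:**
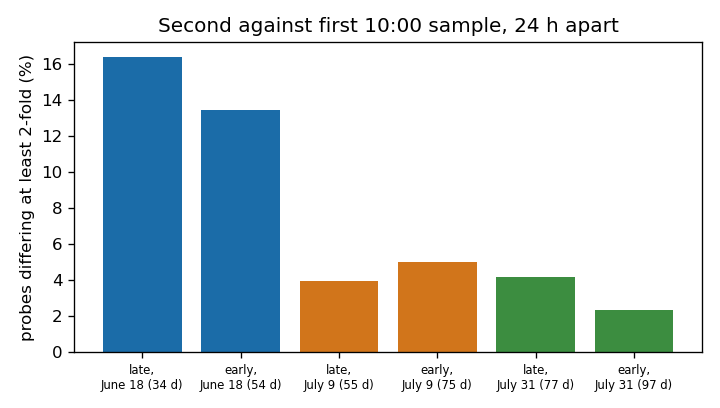
Share of tested probes (vertical axis, percent) that differed at least 2-fold between the second and the first 10:00 sample of each series (horizontal axis, 1 pair of samples per bar). The June 18 series stand at 16.39% and 13.47%, and the others lie between 2.33% and 5.00%.

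On 2 arrays of the 75-day series, which held the samples of 12:00 and 14:00 and those of 8:00 and 10:00 of the second day, the channels were nearly equal. Their median absolute log2 differences were 0.0796 and 0.0768, and 164 and 207 probes differed 2-fold or more. In the 34 other consecutive pairs on 1 array the median was between 0.1251 and 0.2893.

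**Figure D5:**
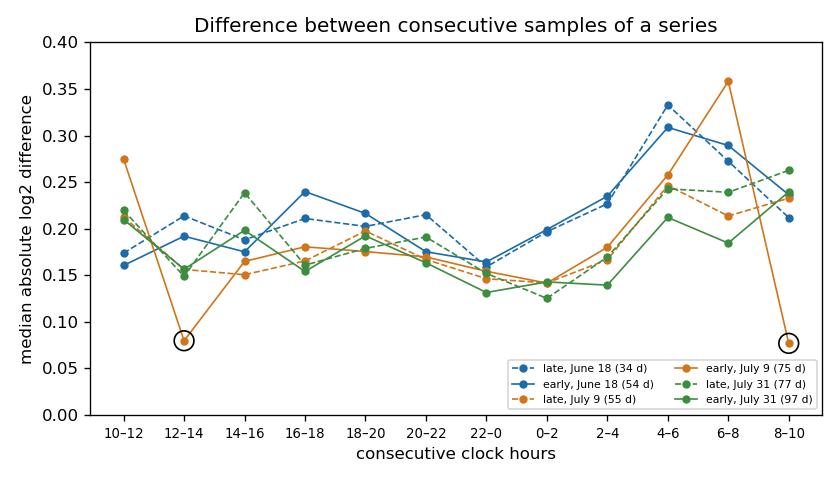
Median absolute log2 difference over the tested probes (vertical axis) between consecutive samples of each series (horizontal axis, clock hours). The circled points are the 2 arrays of the 75-day series, at 0.0796 and 0.0768, and the other pairs on 1 array lie at 0.1251 or above.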

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

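Tests chosen only after the result was seen were that of the scan session, that of little change between the hours with equal channels, and the fit of differences at matched hours with its alternatives. The samples left out in the test of the last morning were also chosen after the data were seen. The slope used for the same RNA replaced a ratio that had been seen not to tell it from slow change.

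The daily curves differed between the 3 dates for 37840 probes, by a test of the difference between groups with no threshold of size. Pair by pair, July 9 against June 18 gave 39857 probes, July 31 against June 18 gave 32166 and July 31 against July 9 gave 136. A difference between scan sessions would leave few changes in the late planting, whose June 18 and July 9 samples shared a session and scanner, but that comparison gave 13699. Plant age as the whole cause would leave few changes at nearly equal age. Between 55 days on July 9 and 54 days on June 18 there were 7690 probes, 0.561 times the 13699 for 55 against 34 days. That pair also differs in planting and slides, and the first 4 samples of the 54-day series were scanned apart. No count of curves without those samples was made for it. Between 54 and 34 days on June 18, where the same samples were scanned apart, the same fit gave 1 probe. Differences at matched hours gave 972 there. Errors in single samples would not recur in the other planting, whose samples are separate, but the change of curve had a correlation of 0.812 across probes between the plantings. An unusual last morning would lose its effect without the last 3 samples, but 37218 probes were left then, against 32579 without 3 evening samples, a ratio of 1.142. Of 100 splits of the dates within plantings none gave as many as the real one (1 of 100 with the real one included). The real split gave 56013 in a fit without array block and the highest of the others gave 3232. The splits moved single samples between dates, so they exclude a chance placement of samples but not a spread between days or slides. What stays open is a difference between single days, such as the weather of those days, since each date is 1 day, the season, and a part of age. That the season or the days changed the leaves' daily curves may be kept as a hypothesis, found and tested on the same data.

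The early minus late difference of level differed between the dates for 16885 probes, by a test of the difference between groups. No explanation was weighed for it. The plantings of July 9 shared a scan session, as did those of July 31, but on June 18 the first 4 samples of the 54-day series were scanned apart from the rest, and without them the June 18 count of levels was 758 in place of 182.

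The daily curves of the plantings differed for 0 probes in limma, with 2809 at an unadjusted p under 0.05. Departures from the fitted curve that both plantings share, which inflate the residual spread, could hide differences. Differences at matched hours, where such departures cancel, gave 3943 probes with a block of arrays, 9127 without it (the count seen first) and 1058 without the 4 samples with nearly equal channels. Turning the sign of the differences by pair of arrays or by hour gave at most 88 probes in 99 draws, against 9249 for the real ones (1 of 100). This excludes chance signs of single pairs of arrays or hours. Slides ran along the hours and differed between the plantings, and such turning breaks their runs, so offsets between slides are not excluded. These draws used no block and a simpler moderation of the variances, with no trend, which is why the real count differs from 9127. On simulated values this fit made 18 wrong calls beside 99 of 200 right ones. The counts by date (972, 94 and 18479) were not tested against each other. For the fit of all series, 2 of 100 splits of the plantings gave as many probes as the real one (59, against 1196 for the highest other). That other split swapped plantings within hours and called many times the real count, which points to a structure of the samples whose source was not tested, so no difference between the plantings is read from this fit. The median ratio of the difference was 1.40 averaged over the dates, and 1.86 on June 18, 2.59 on July 9 and 1.67 on July 31 over the probes of each date. Whether it reflects the plants, their place in the field, the slides or the 1 day sampled was not tested.

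The nearly equal channels of the 2 arrays of the 75-day series were weighed as a technical pattern, and no biological explanation but slow change was tested. Little change between these hours would give small differences in other series at the same hours, but those were 1.868 to 3.419 times larger in 10 comparisons. The same RNA in both channels would leave none of the change that other series show between these hours. Across probes, the slope of the difference between the channels on the mean difference of the other 5 series was -0.02 and -0.026, against 0.413 to 1.051 for the other series, which is consistent with it. The ratio to the difference between probes of identical sequence, at most 0.703, was below that of the 70 other consecutive pairs (0.862 or more), but 5 of these were also below 1, so that ratio alone does not tell the same RNA from slow change. The sample labelled 12:00 correlated best with the 14:00 sample in 4 of the 5 other series, and that labelled 8:00 with the 10:00 sample in 4 of 5. A candidate explanation is that the later sample was labelled with both dyes, and a mix-up at another step stays open. Without these 4 samples the July 9 planting count fell from 837 to 505.

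In each of the following comparisons of levels 1 of 100 splits, the real one, gave as many probes. The splits moved single samples between series, so they exclude a chance placement of samples only. Each planting on a date is 1 series without replicates, so a chance spread between series, slides or days is not excluded. With slide as a fixed block, 9 of the 182 calls on June 18 recurred in the same direction and 77.5% kept their sign. The real and highest other counts were 178 and 64 for the plantings on June 18, 960 and 0 on July 9, 2763 and 1637 on July 31, 4810 and 716 for July 9 against June 18, 2018 and 659 for July 31 against July 9, 5360 and 1331 for 55 against 54 days, and 621 and 365 for 77 against 75 days. For the shared rhythm, orders of the sampling hours gave at most 1474 probes against 30702 (1 of 100), in a fit without the array block. This excludes a chance order of the hours only. Such orders break the runs of consecutive samples, arrays and slides, so a drift along the hours that recurred across series is not excluded. For the 24 h repeat, 2 of 32 sign patterns gave as many probes as the real one, with 130 for the real one and 468 for the highest other, so chance could not be excluded. The highest pattern turned the signs of the 54, 77 and 97-day series.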

How the results depend on the processing

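Slide as a fixed block and matched-hour differences were chosen after seeing the data. So was leaving out samples, except for the last sample of each series and each whole series, which were set before. Of 205 counts under alternatives 168 lay within 1.5 times the reported count and 37 did not. Values of named probes were taken under 12 of the alternatives set before the data were examined. They were not taken with a whole series left out or under any alternative chosen after seeing the data. Of these 359 values 356 kept their direction and side of the threshold, 3 lost significance and 0 reversed. The 3 were eAry2_40456, 44kb3_10697 and eAry1_31375 with slide as the random block. Unless stated, the cause was not tested.

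With the scanner's processed signals the shared rhythm gave 46713 probes. Level counts were 812, 1965 and 6408 for the plantings on June 18, July 9 and July 31, 11302 and 6093 for the dates, 12272 and 1542 at matched age, and 254 for the 24 h repeat. With the authors' values they were 599, 1724 and 5534, 9472 and 5176, 10121 and 1280, and 219. The share higher on July 31 in the early planting moved from 74.3% to 60.9% and 60.6%, and that higher on July 9 against June 18 from 45.4% to 55.4% with the processed signals. The 24 h repeat gave 81 probes with no filter on dim probes and 217 with a filter at 39 samples.

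With no array block the planting curves gave 64 probes and the June 18 level 300. With slide as the random block these were 1 and 28, July 9 gave 2054 and 77 against 75 days 238. With 12 h harmonics the planting curves gave 3. Slide as a fixed block gave levels of 71 on June 18, 12993 on July 9, 4317 on July 31, 9279 for July 9 against June 18 and 16895 for 55 against 54 days. Matched-hour differences gave 3943 for the planting curves, 9127 without a block of arrays and 1058 without the 4 samples with nearly equal channels. Without the last 3 samples of each series the planting curves gave 53. Without the first 4 samples of the 54-day series the June 18 count was 758, and without the 4 samples of the 75-day series the July 9 count was 505.

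Slot as a block for the pairing gave 250, 957 and 2778 for the plantings, 4889 and 1999 for the dates, and 4884 and 603 at matched age. The median of all probes of a gene was not run. Signal over background, lowest in the 34-day series, limits what dim probes show.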

Other observations

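Overlapping probes were compared as a measure of repeatability within the arrays. Of 92489 pairs that share at least 30 bases on the same strand, both were rhythmic in 14297, and 98.9% of these peaked within 2 h of each other, with a median difference of 0.07 h. Of 980 pairs on opposite strands both were rhythmic in 57, of which 20 (35.1%) peaked within 2 h and 27 (47.4%) lay at least 6 h apart. Of 100000 random pairs of rhythmic probes, 17888 peaked within 2 h and 50181 lay at least 6 h apart.

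Among the probes whose level differed, 49.7% (plantings on July 9) to 68.9% (July 9 against June 18) had a shared rhythm, against 31.2% of all tested probes. Both calls need at least 2-fold, and the probes were not matched for signal. No link between rhythm and level is therefore read from these shares.

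Probe 44kb3_23620 had log2 means of 6.88, 9.34, 10.70, 12.56, 14.81 and 14.81 at 34, 54, 55, 75, 77 and 97 days after transplanting.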
